A study of Mus musculus with 4 samples.

How the data were processed

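Poly(A) RNA from mouse P14 CD8 T cells was sequenced in 4 libraries, 2 from cells carrying the empty retroviral vector MIG and 2 from cells carrying MIG with BATF. Groups and replicate numbers came from the sample titles. The series' design text calls the libraries of a group biological replicates, and it does not say whether they came from separate mice. The replicates of a group differed by more than counting noise, with a chi-square per gene of 17.7 in MIG over 12919 genes and 9.49 in BATF over 12794 genes, so no library was taken for a second deposit of another. Each library counted as 1 sample because of the design text, and the p-values measure the spread between these libraries, which may in part be technical.

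TopHat2 2.1.1, Cufflinks 2.2.2, Cuffdiff and the genome build mm9 are named in the submitters' processing notes. The gene annotation and the strandedness of the libraries are not given in the sources used here. The deposited table is a long Cuffdiff table with 1 value per gene, condition and replicate, per the file headers. It numbers the replicates 0 and 1, while the titles number them 1 and 2. The condition ties each library to its group. No label ties the table's number to a title, and 0 was read as replicate 1 and 1 as replicate 2, so that replicate numbers here only name libraries. The other reading would exchange the names of replicates 1 and 2 in both groups, and would change neither the comparison of the groups nor the block by number.

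The deposited table gives estimated counts, that is the fragments that the authors' Cuffdiff run assigned to each gene in each library before scaling, per the file headers. Of these values, 97.6% were whole numbers (equality to 0 decimals), and the rest carried fractions. The table also holds a scaled fragment signal, the estimated count times 1 factor per library set by the authors' run, and the deposited FPKM, which divides that signal by transcript length, per the file headers. The authors' factors were 0.889 and 1.02 for MIG and 1.11 and 0.986 for BATF, and they served here only as a check of the column's meaning. Serbp1 was the 1 gene whose quantification status was not OK, in 3 of its 4 entries, and its counts were kept.

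Library totals were 24795714 and 20354623 fragments in MIG and 19004726 and 21835968 in BATF. The table listed 24312 genes, of which 1538 had 0 fragments in every library. For the comparison, estimated counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr and libraries scaled by the trimmed mean of M values (TMM), with factors from 0.989 to 1.01. The quasi-likelihood test (glmQLFit and glmQLFTest) compared BATF with MIG without a covariate. P-values were adjusted by the Benjamini-Hochberg method over the 13008 genes tested, with a threshold of 0.05. Levels are TMM-scaled CPM (edgeR's cpm function on the TMM-scaled library totals), given as mean ± SD over the 2 libraries of a group. The standard error (SE) of a log2 fold change is the unshrunk coefficient divided by the square root of the test's F statistic. The biological coefficient of variation was 11.3%. With 2 libraries against 2, a two-sided permutation test of 1 value cannot give a p below 0.333, so no such test was run, and the reported p-values rest on the spread that edgeR shares across genes.

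A set of 27 gene lists with 668 entries was fixed before the data were examined, together with the rule for named genes, the main test and the alternatives listed below except 2 added list tests; 662 entries matched a listed gene. The lists cover AP-1 and IRF factors, cytotoxic effector molecules, cytokines and chemokines, cytokine receptors, naive and memory T cell genes, effector differentiation factors, inhibitory receptors and exhaustion genes, costimulatory molecules, homing and adhesion, glycolysis, oxidative phosphorylation, fatty acid oxidation and NAD metabolism, cholesterol synthesis, cell cycle, interferon-stimulated genes, apoptosis regulators, T cell receptor signalling, Th2, Th17 and Tfh genes, unfolded protein and amino acid stress, heat shock and immediate early stress, ribosomal proteins and housekeeping genes. Markers of other cells that the sort could hold make up the other 5 lists: B cells, myeloid and dendritic cells, CD4 and regulatory T cells, NK and gamma-delta T cells, and erythroid, platelet and stromal cells. Some genes stand in more than 1 list, among them Maf, Icos and Il6ra. The 22 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Each list is also described by the members that passed the edgeR test over all genes and by the members that passed when p-values were adjusted over the list alone.

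The rule for named genes had 3 parts. Batf and 17 further genes were taken whatever their values. The 12 largest rises and the 12 largest falls were taken among genes past the threshold with a mean of at least 5 CPM whose BATF libraries lay on one side of both MIG libraries, leaving out small RNAs and unnamed gene models. From each list, up to 4 members past the threshold with a mean of at least 5 CPM and the smallest adjusted p were added. This gave 48 genes, of which 2 are left out of the text. Other genes are named as members of a count or as chosen after their values were seen.

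Alternatives were DESeq2 1.42.0 with its own size factors, DESeq2 size factors or upper-quartile factors in edgeR, TMM without the 50 most abundant genes and Batf, no filter on low counts, a mean of at least 5 CPM, limma on log2 of the deposited FPKM with a pseudocount of 1 or 0.1 (mean FPKM at least 1), limma-voom, a replicate block, and each of the 4 libraries left out in turn. Under upper-quartile factors and the trimmed TMM the list tests were added after the data had been seen.

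The scripts were tested on simulated counts drawn from the means and library sizes of these 4 libraries with 200 genes changed. The changed genes were drawn among those with a mean of at least 1 CPM. For BATF against MIG, over 12684 genes, edgeR recovered 34.3% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 98.5% of those changed 4-fold, with 8 false calls among 150. Without any change it called 0 of 12744 simulated genes. With the 200 genes changed DESeq2 called 154 genes, near edgeR's 150, but in the real data it called 345 against 142. The recovery rates may therefore not carry over to the real data. In a simulation that shifted 1 list, camera called that 1 list. The simulated genes were drawn independently, so this does not test camera's preset correlation where genes vary together.

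GC content and transcript length for 1 check came from the longest transcript of each gene symbol in an annotation of another build (GENCODE M21). No genomic coordinates are given, because the deposited values refer to mm9 and the annotation at hand does not. Fragments from genes with close copies, such as the granzymes, the interferon-inducible GTPases, Ctla2a and Ctla2b and the ribosomal proteins, were divided by estimation, so their levels are less certain than those of single-copy genes. The same holds for genes that overlap on opposite strands. Simulations and tests used fixed seeds, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.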

Results

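Gene expression was measured by poly(A) RNA sequencing in P14 CD8 T cells, mouse T cells whose transgenic receptor recognises the gp33 peptide of lymphocytic choriomeningitis virus. The cells, on a C57BL/6 background, received 100 ng/ml gp33 for 1 day before spin transduction with MIG, a retrovirus that expresses GFP, or with MIG carrying BATF. They stayed activated for 1 more day, expanded for 2 days in 10 ng/ml IL-2, and were sorted as CD8+ GFP+ before 2 final days in 1 ng/ml IL-2. BATF is a basic leucine zipper factor of the AP-1 family, which pairs with JUN proteins and binds DNA together with IRF4. Each group had 2 libraries. The MIG libraries held 24795714 and 20354623 fragments and the BATF libraries 19004726 and 21835968, and between 12872 and 13230 genes had at least 10 fragments in a library. The 10 most abundant genes took 5.42% to 5.67% of the fragments of a library. The comparison asks which transcripts differ between CD8 T cells overexpressing BATF and cells with the empty vector after the same culture.

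The overexpressed gene was measured first. Batf stood at 36.1 and 26.5 CPM in the MIG libraries and at 1342 and 934 CPM in the BATF libraries, a 36.3-fold difference (log2 fold change 5.18 ± 0.24 SE, adjusted p = 0.00188 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 2 per group). Fragments of the vector's copy and of the cells' own Batf were not separated, and the species of the BATF sequence is not given in the sources used here.

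Cells with added BATF carried more mRNA for the surface receptors Tnfrsf8 (CD30), Icos, Il2ra, Lag3 and Havcr2 (TIM-3), and for the transcription factors Maf, Prdm1, Myb and Pparg. They carried less mRNA for Foxo1, a transcription factor of quiescent T cells, for Ccr7, the receptor that guides T cells to lymph nodes, and for the Tec family kinase Txk. Tnfrsf8 rose from 3.47 ± 2.09 to 92.7 ± 12.9 CPM and Il2ra from 297 ± 3.35 to 640 ± 76.2 CPM (SD, n = 2 per group), while Foxo1 fell from 227 ± 1.68 to 148 ± 2.68 CPM. Of 13008 genes tested, 142 changed, 115 upward and 27 downward, and 94 of them changed at least 2-fold, 82 upward and 12 downward. In each of the 142 genes both BATF libraries lay on the same side of both MIG libraries. A call with 2 libraries per group nearly requires this, so it adds no support. Groups failed to overlap in 5030 of the 13008 tested genes, where chance alone gives a share of 33.3%. DESeq2 called 345 genes, and limma on log2(FPKM + 1) called 36. In fits with 1 library left out, here and below, the lone library of a group is assumed to vary like the other group. A fit with the replicate number as a block leaves 1 residual degree of freedom. Passing only in such a fit is not taken as a change. Without MIG replicate 1 edgeR called 251 genes, without MIG replicate 2 it called 589 (320 higher, 269 lower), without BATF replicate 1 it called 275 and without BATF replicate 2 it called 248, and 116 to 142 of the 142 genes were called again in these fits.

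**Figure D1:**
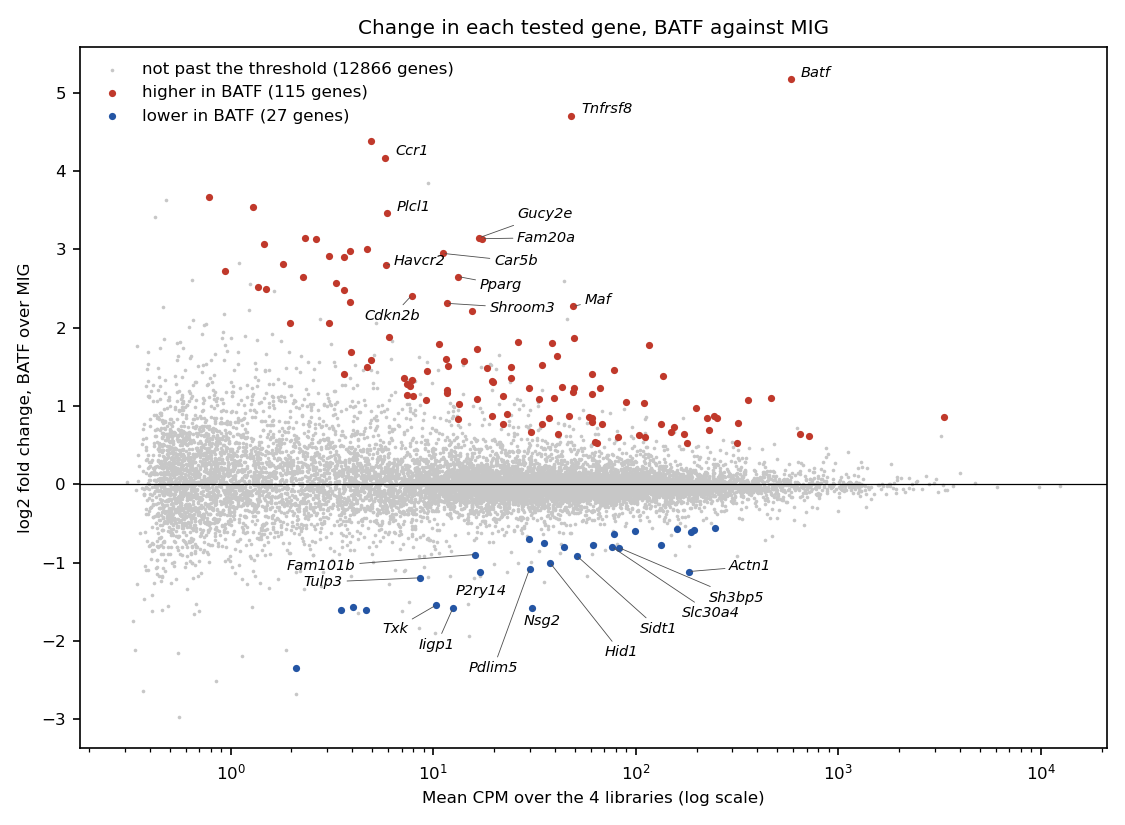
Each point is 1 of the 13008 tested genes, with its mean CPM over the 4 libraries on a log axis and its log2 fold change in BATF over MIG on the other axis. The 115 genes that rose are red and the 27 that fell are blue, and Batf (5.18) and Tnfrsf8 (4.71) lie farthest above 0 among the named genes.

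After Batf and Tnfrsf8 (log2 fold change 4.71 ± 0.33 SE), the largest rise among genes with at least 5 CPM was that of Ccr1, a receptor for inflammatory chemokines, from 0.613 ± 0.231 to 11.0 ± 3.28 CPM (log2 fold change 4.17). Plcl1, a catalytically inactive relative of phospholipase C, rose from 0.983 to 10.8 CPM. Gucy2e, a membrane guanylate cyclase, rose from 3.39 to 30.5 CPM and Fam20a, a pseudokinase of the secretory pathway, from 3.58 to 31.4 CPM. Car5b, a mitochondrial carbonic anhydrase, rose from 2.55 to 19.9 CPM. Pparg, a nuclear receptor that controls lipid genes, rose from 3.65 ± 0.129 to 23.0 ± 1.00 CPM, with a log2 fold change of 2.65 ± 0.15 SE. Cdkn2b, which encodes the cyclin-dependent kinase inhibitor p15, and Shroom3, a regulator of cell shape, rose by log2 fold changes of 2.41 and 2.31. For the genes of this paragraph the adjusted p from edgeR's quasi-likelihood test lay between 0.00188 (Batf) and 0.0205 (Car5b).

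The 12 largest falls among called genes with a mean of at least 5 CPM were smaller. Called genes below that level, among them Myl10 (log2 fold change −2.35), fell further. Iigp1, an interferon-inducible GTPase, fell from 18.8 ± 2.03 to 6.27 ± 2.24 CPM (log2 fold change −1.59, edgeR adjusted p = 0.0406). Nsg2, a gene of endosomal trafficking, fell from 46.2 ± 0.505 to 15.5 ± 0.0431 CPM (edgeR adjusted p = 0.00523), and Txk from 15.4 ± 0.201 to 5.26 ± 0.427 CPM. Tulp3, which carries receptors into cilia, and P2ry14, a receptor for UDP-sugars, had log2 fold changes of −1.20 and −1.12. The actin-bound proteins Actn1 and Pdlim5 fell as well, Actn1 from 251 ± 39.6 to 116 ± 13.4 CPM and Pdlim5 from 40.8 to 19.2 CPM. Hid1 and Sidt1 followed with −1.00 and −0.91, and Sh3bp5 and the zinc transporter Slc30a4 with −0.81 and −0.80. Fam101b had a log2 fold change of −0.90, and its call was lost without MIG replicate 1 (edgeR adjusted p = 0.0501) and without BATF replicate 1 (edgeR adjusted p = 0.0838).

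Among AP-1 and IRF factors, the family of BATF and its partners, 2 of 19 tested members rose, Batf itself and Maf, and 0 fell. Adjusted over the list alone, 5 rose and 2 fell. Maf, a factor of T helper and regulatory programmes, rose from 16.9 ± 5.73 to 81.3 ± 29.7 CPM (log2 fold change 2.27, edgeR adjusted p = 0.0263). The partners of BATF did not pass in the fit without a block. Jun stood at 69.1 ± 11.0 CPM in MIG and 59.2 ± 22.6 in BATF, Junb at 145 ± 6.45 and 161 ± 26.3, and Irf4 at 54.4 ± 8.64 and 70.8 ± 14.3. With the replicate number as a block, Irf4 (log2 fold change 0.38, edgeR adjusted p = 0.000121) and Jun (−0.26, 0.0185) passed and Junb did not (0.15, 0.292). The sign of Jun (−0.22) turned without BATF replicate 1 (0.13), and that of Junb (0.16) without BATF replicate 2 (−0.022). Batf3, a paralog of Batf, stood at 4.12 ± 1.63 and 12.9 ± 5.39 CPM and missed the threshold with all libraries (log2 fold change 1.63, edgeR adjusted p = 0.123). It passed in DESeq2 (0.000215), with no filter on low counts (0.00633) and with the block (2.06e-24), a fit with 1 residual degree of freedom. Its log2 fold change was 2.12 without MIG replicate 1 and 1.28 without MIG replicate 2. It was 1.13 without BATF replicate 1 and 2.01 without BATF replicate 2. EdgeR called 3, 4, 4 and 4 members of the list upward and 0, 3, 0 and 0 downward without MIG replicate 1, MIG replicate 2, BATF replicate 1 and BATF replicate 2 in turn. Batf, the overexpressed gene, is a member, so it enters these upward counts as well as the list's mean and camera test, and no values without it were computed. The list's median log2 fold change was −0.04, its mean 0.52, and camera, pointing upward, gave an adjusted p of 0.552. That median turned to 0.115 without MIG replicate 2, 0.125 without BATF replicate 1 and 0.017 without BATF replicate 2. It was −0.0622 without MIG replicate 1.

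Of 20 costimulatory molecules tested, Tnfrsf8 and Icos rose and 0 fell, and 3 rose and 0 fell adjusted over the list alone. The edgeR count was 2, 4, 4 and 2 upward and 0 downward without MIG replicate 1, MIG replicate 2, BATF replicate 1 and BATF replicate 2 in turn. Icos, a CD28 relative that binds ICOS ligand, rose from 75.7 ± 5.64 to 198 ± 9.88 CPM (log2 fold change 1.38 ± 0.09 SE, edgeR adjusted p = 0.00523). The list's median was 0.08 and its camera adjusted p was 0.200. Of 25 inhibitory receptors and exhaustion genes tested, Lag3 and Havcr2 rose and 0 fell, and adjusted over the list alone 4 rose and 2 fell. In the same order of libraries left out, edgeR called 3, 5, 4 and 3 of them upward and 1, 1, 1 and 0 downward. Lag3, which binds MHC class II, rose from 37.9 ± 3.49 to 84.4 ± 3.09 CPM, and Havcr2 rose from 1.47 ± 0.524 to 10.2 ± 3.60 CPM. Pdcd1, which encodes PD-1, stood at 9.90 ± 2.33 CPM in MIG and 28.5 ± 14.0 in BATF and did not pass (edgeR adjusted p = 0.123), although it passed without MIG replicate 2 (0.00279), without BATF replicate 1 (6.22e-07), with no filter on low counts (0.00439) and with the replicate number as a block (3.75e-25). Tox, a factor of exhausted T cells, was low at 3.15 ± 1.79 and 2.18 ± 0.552 CPM, and its log2 fold change of −0.51 turned to 0.21 without MIG replicate 2. The list's median was −0.09 against a mean of 0.16, and camera gave an adjusted p of 0.967 in the upward direction. That median turned to 0.221 without MIG replicate 2 and 0.0886 without BATF replicate 1. It was −0.165 without MIG replicate 1 and −0.147 without BATF replicate 2.

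Cytokine receptors moved in both directions. Of 27 tested, Il2ra and Il1r2 rose and Il6ra fell, and adjusted over the list alone 3 rose and 7 fell. Calls by edgeR without MIG replicate 1, MIG replicate 2, BATF replicate 1 and BATF replicate 2 in turn were 2, 3, 2 and 2 upward and 1, 6, 2 and 2 downward. Il2ra, the alpha chain of the IL-2 receptor, had a log2 fold change of 1.11 ± 0.10 SE (edgeR adjusted p = 0.00932). Il1r2, a decoy receptor for IL-1, rose from 0.106 ± 0.0812 to 1.47 ± 0.135 CPM, and Il6ra, the IL-6 receptor, fell from 6.99 ± 1.10 to 2.31 ± 0.537 CPM. Both lie below 5 CPM on average and are named as members of this count, and Il6ra was not called without MIG replicate 1 (edgeR adjusted p = 0.0653). The interferon receptor chains Ifnar1, Ifnar2 and Ifngr2 were among the 7, with log2 fold changes of −0.45, −0.34 and −1.20, and were chosen after their values were seen. Il7r, the IL-7 receptor, stood at 197 ± 64.9 and 211 ± 47.4 CPM, and its log2 fold change of 0.09 turned to −0.22 without MIG replicate 2 and to −0.16 without BATF replicate 1. The median of the list was −0.10, its mean 0.03, and camera gave an adjusted p of 0.255 in the downward direction.

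Of 26 naive and memory T cell genes tested, 5 fell, 1 rose and 20 did not pass, and adjusted over the list alone 10 fell and 2 rose. Without MIG replicate 1, MIG replicate 2, BATF replicate 1 and BATF replicate 2 in turn, edgeR called 5, 15, 8 and 4 downward and 2 upward each time. Txk, Actn1, Foxo1, Ccr7 and Il6ra fell, of which Ccr7 (169 ± 19.4 to 99.0 ± 12.1 CPM) and Il6ra are named as members of the count. The call of Foxo1 (log2 fold change −0.61, edgeR adjusted p = 0.0229) was lost without BATF replicate 1 (0.0604) or BATF replicate 2 (0.0620), that of Ccr7 without BATF replicate 2 (0.0671) and that of Il6ra without MIG replicate 1 (0.0653). The gene that rose was Myb, a transcription factor of progenitor and memory T cells, from 11.6 ± 2.39 to 41.2 ± 3.68 CPM (log2 fold change 1.82). Tcf7, which encodes TCF-1, stood at 413 ± 134 CPM in MIG and 219 ± 17.4 in BATF (log2 fold change −0.91, edgeR adjusted p = 0.123), and it passed without MIG replicate 1 (0.0299), MIG replicate 2 (1.91e-06) or BATF replicate 1 (0.00381), with no filter on low counts (0.00561) or with the replicate number as a block (1.88e-26). Eomes, a T-box factor, stood at 27.0 ± 16.3 and 13.2 ± 8.48 CPM and did not pass with all libraries, but did without BATF replicate 2 (log2 fold change −1.91, edgeR adjusted p = 0.0176) and with the replicate number as a block (2.48e-13). Its log2 fold change of −1.02 shrank to −0.23 without MIG replicate 2 (0.834) and to −0.49 without BATF replicate 1 (0.979), and was −1.54 without MIG replicate 1 (0.137). As a list, 23 of the 26 members had a negative log2 fold change, with a median of −0.43, and camera called it downward (adjusted p = 4.64e-06), but not with an estimated correlation (adjusted p = 0.737 with an estimated correlation). Without MIG replicate 1 the camera adjusted p was 0.0503.

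Of 28 effector differentiation factors, Rbpj, Prdm1 and Hif1a rose and 0 fell, and adjusted over the list alone 5 rose and 1 fell. EdgeR's upward calls were 4, 6, 3 and 3 and its downward calls 0, 2, 0 and 0 without MIG replicate 1, MIG replicate 2, BATF replicate 1 and BATF replicate 2 in turn. Prdm1, which encodes the repressor BLIMP-1, rose from 13.7 ± 3.11 to 35.0 ± 5.20 CPM (log2 fold change 1.35 ± 0.19 SE, edgeR adjusted p = 0.0279). Rbpj, the DNA-binding factor of the Notch pathway, rose from 236 ± 23.6 to 408 ± 9.35 CPM. Hif1a, the oxygen-regulated factor, rose from 260 ± 1.79 to 374 ± 25.5 CPM, and its call was lost without BATF replicate 1 (edgeR adjusted p = 0.248) or BATF replicate 2 (0.0736). Tbx21, which encodes T-bet, stood at 100.1 ± 15.9 and 116.5 ± 17.1 CPM and did not pass, except with the replicate number as a block (log2 fold change 0.22, edgeR adjusted p = 0.0435). The list's median was 0.04 and its camera adjusted p was 0.298.

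Cytotoxic effector molecules did not pass singly. Of 18 tested, edgeR called 0, with 4 higher and 1 lower at an unadjusted p under 0.05, DESeq2 called 2 upward and limma-voom called 0. Adjusted over the list alone, 2 rose (Cst7 and Klrk1). With edgeR, without MIG replicate 1, MIG replicate 2, BATF replicate 1 and BATF replicate 2 in turn, 1, 3, 2 and 1 members were called upward and 0, 0, 1 and 0 downward. Gzmb, which encodes granzyme B, stood at 2540 ± 283 CPM in MIG and 3898 ± 1103 in BATF (log2 fold change 0.62, edgeR adjusted p = 0.245) and passed without MIG replicate 2 (0.0130) or BATF replicate 1 (0.00145), in DESeq2 (0.0128), with no filter on low counts (0.0441) or with the replicate number as a block (6.42e-12). Without BATF replicate 2 its log2 fold change was 0.30 (0.895). Prf1, which encodes perforin, stood at 8.61 ± 0.732 and 9.57 ± 0.408 CPM. The list's median was 0.08 and its camera adjusted p was 0.552. Among 19 cytokines and chemokines edgeR called 0, with 2 higher and 2 lower at an unadjusted p under 0.05, DESeq2 called 1 upward and 1 downward and limma-voom called 0, and adjusted over the list alone 2 rose and 1 fell. In the same order, edgeR called 1, 3, 2 and 1 of them upward and 1, 1, 1 and 2 downward. Ifng, which encodes interferon gamma, was low, at 2.85 ± 0.595 CPM in MIG and 1.73 ± 0.168 in BATF. The median of the cytokine list was −0.10 and its mean 0.01, and camera gave an adjusted p of 0.967 in the upward direction. That median turned to 0.21 without MIG replicate 1, 0.42 without MIG replicate 2 and 0.11 without BATF replicate 1. It was −0.25 without BATF replicate 2.

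**Figure D2:**
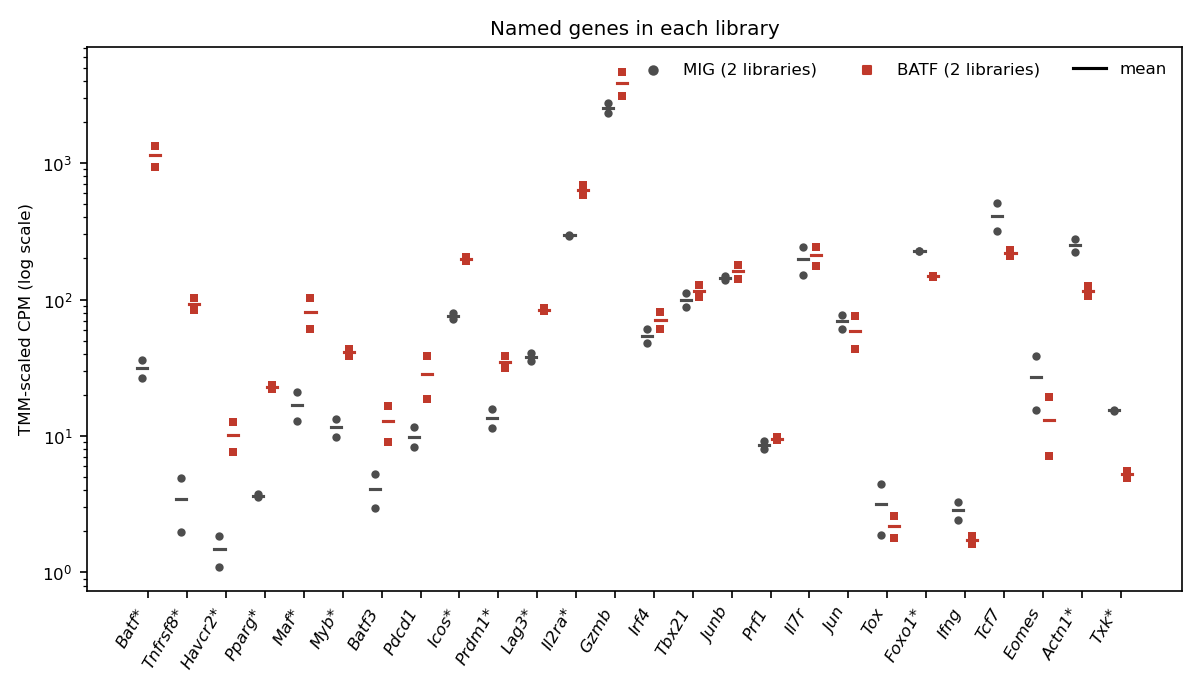
TMM-scaled CPM (log axis) of named genes in each of the 4 libraries, grey circles for MIG and red squares for BATF, with a short line at each group's mean and an asterisk on genes past the threshold. Batf lies at 26.5 and 36.1 CPM in MIG and at 934 and 1342 CPM in BATF, while the 2 values of Il7r or Jun in one group overlap those in the other.

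Interferon-stimulated genes were lower in BATF as a list, by small amounts per gene. Of 30 tested, 28 had a negative log2 fold change, with a median of −0.43. Camera called the list downward (adjusted p = 2.08e-12), and the call was lost with an estimated correlation (adjusted p = 0.301 with an estimated correlation, unadjusted p = 0.0137). Over all genes edgeR called 0 members, with 15 lower and 0 higher at an unadjusted p under 0.05, DESeq2 called 5 downward and limma-voom called 0, and adjusted over the list alone 12 fell. The edgeR count of members that fell was 1 without MIG replicate 1, 8 without MIG replicate 2, 2 without BATF replicate 1, 1 without BATF replicate 2, 4 with no filter on low counts and 16 with the replicate number as a block, so that it depends on the libraries and the model. Rtp4 stood at 13.1 ± 3.91 CPM in MIG and 5.73 ± 1.39 in BATF, Zbp1, a sensor of Z-form nucleic acids, at 53.0 ± 5.77 and 34.6 ± 1.06, and Trim30a at 90.0 ± 0.869 and 67.0 ± 2.23. These 3 members were chosen after their values were seen.

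Glycolysis genes were higher as a list, again by small amounts. Of 23 tested, Slc16a3, the lactate exporter MCT4, rose from 33.3 ± 3.02 to 60.8 ± 0.341 CPM (log2 fold change 0.87, edgeR adjusted p = 0.0210) and 0 fell, and adjusted over the list alone 7 rose and 1 fell. The one that fell in that count was Slc16a1, another monocarboxylate carrier. With the replicate number as a block edgeR called 10 members upward and 1 downward. Without MIG replicate 1 or MIG replicate 2 edgeR called 2 members upward. Tpi1 stood at 304 ± 16.4 and 420 ± 14.2 CPM and Eno1 at 1172 ± 3.73 and 1422 ± 47.4, both enzymes of the pathway and both chosen after their values were seen. The list's median was 0.21 and camera called it upward (adjusted p = 0.00501), but not with an estimated correlation (adjusted p = 0.737 with an estimated correlation). The call was also lost without MIG replicate 2 (camera adjusted p = 0.221), BATF replicate 1 (0.0505) or BATF replicate 2 (0.0673). Oxidative phosphorylation, with 33 members tested, had a median of −0.04 and a camera adjusted p of 0.494, and edgeR, DESeq2 and limma-voom each called 0 members, with 0 at an unadjusted p under 0.05. For fatty acid oxidation and NAD metabolism (23 tested, median 0.03, camera adjusted p = 0.342) edgeR called 0 members, with 4 higher and 1 lower at an unadjusted p under 0.05, DESeq2 called 1 upward, limma-voom called 0, 1 rose adjusted over the list alone, and edgeR called 1 upward without MIG replicate 2 or BATF replicate 2. For cholesterol synthesis (20 tested, median −0.10, camera adjusted p = 0.214) edgeR, DESeq2 and limma-voom called 0 members, with 3 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone, and edgeR called 1 downward without MIG replicate 2.

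The cell cycle list gave no sign of a difference at this depth. Of 34 members tested, edgeR, DESeq2 and limma-voom each called 0, with 0 at an unadjusted p under 0.05, and the median was −0.03 (camera adjusted p = 0.870). Of 24 apoptosis regulators 1 rose and 0 fell, 1 rose and 1 fell adjusted over the list alone, and the median was −0.06 (camera adjusted p = 0.894). Of 31 T cell receptor signalling genes edgeR called 0, with 1 higher and 9 lower at an unadjusted p under 0.05, DESeq2 called 1 downward and limma-voom called 0, 1 fell adjusted over the list alone, and the median was −0.10 (camera adjusted p = 0.171). Of 14 Th2, Th17 and Tfh genes Maf and Icos rose and 0 fell, 4 rose adjusted over the list alone, and the median was 0.19 (camera adjusted p = 0.171). Camera called that list upward without MIG replicate 2 (adjusted p = 0.0294, or 0.861 with an estimated correlation, median 0.47), without BATF replicate 1 (0.0189, or 0.849 with an estimated correlation) and at a mean of at least 5 CPM (0.000236, or 0.555 with an estimated correlation). Of 29 homing and adhesion genes edgeR called 0, with 5 higher and 3 lower at an unadjusted p under 0.05, DESeq2 called 2 upward and 1 downward and limma-voom called 0, 1 rose adjusted over the list alone (Itgax), and the median was −0.02 (camera adjusted p = 0.927). Leaving out MIG replicate 1, MIG replicate 2, BATF replicate 1 and BATF replicate 2 in turn, edgeR called 0, 2, 2 and 0 T cell receptor signalling genes upward and 1, 5, 1 and 2 downward, and 0, 2, 1 and 0 homing genes upward and 0, 1, 1 and 0 downward. It called 3 Th2, Th17 and Tfh genes upward without MIG replicate 2 and 1 apoptosis regulator downward without MIG replicate 1.

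Stress and control lists had medians close to 0 with all libraries, and edgeR, DESeq2 and limma-voom each called 0 of their members, also adjusted over each list alone with edgeR. Unfolded protein and amino acid stress (30 tested) had a median of −0.01, a mean of 0.04 and a camera adjusted p of 0.927 in the upward direction, with 3 higher and 1 lower at an unadjusted p under 0.05. Heat shock and immediate early stress (20 tested) had a median of 0.00, a mean of 0.11 and a camera adjusted p of 0.967, with 1 higher and 1 lower at an unadjusted p under 0.05. Ribosomal proteins (51 tested) had a median of −0.04 and a camera adjusted p of 0.200, with 0 at an unadjusted p under 0.05. Camera called them downward without MIG replicate 2 (adjusted p = 0.000515, or 0.861 with an estimated correlation, median −0.10), and the median turned to 0.026 without MIG replicate 1. The 14 housekeeping genes had a median of 0.00 and a camera adjusted p of 0.967, with 1 higher at an unadjusted p under 0.05. Without MIG replicate 2 edgeR called 1 member each of the heat shock and housekeeping lists upward and 1 each of the ribosomal and unfolded protein lists downward, and it called 1 ribosomal protein upward without MIG replicate 1 and 1 heat shock member upward without BATF replicate 1.

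**Figure D3:**
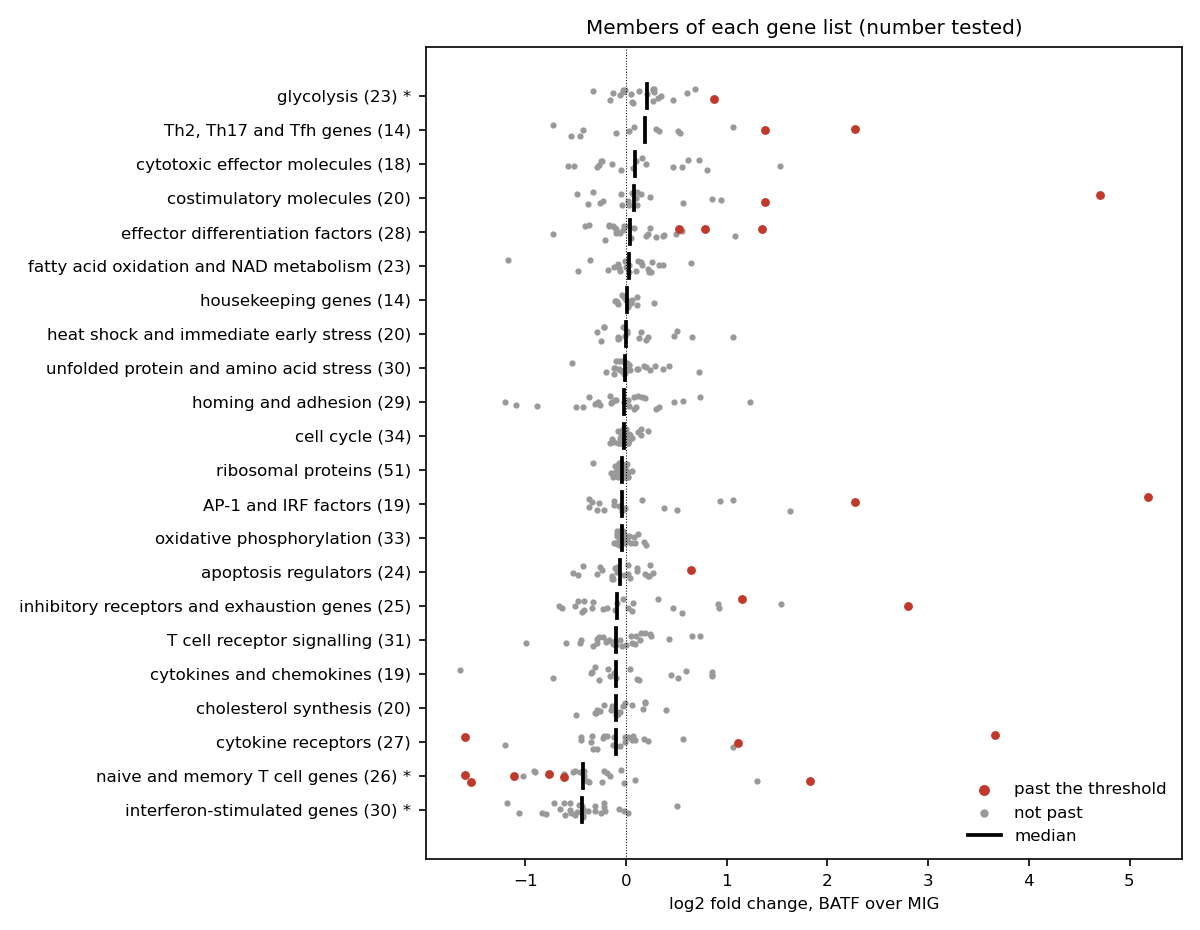
Log2 fold changes in BATF over MIG of the tested members of the 22 lists tested, each point a gene, red where it passed the threshold over all genes, with a black bar at the list's median and an asterisk on the 3 lists that camera called. Interferon-stimulated genes and naive and memory T cell genes have medians of −0.43, and glycolysis has a median of 0.21.

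Markers of other cells were scarce, with 3 or 4 tested members in each of the 5 lists and too few for camera with all libraries. With all libraries and no block, edgeR and limma-voom called 0 of them. With the replicate number as a block, edgeR called H2-Ab1 (adjusted p = 6.8e-22), Xcr1 (6.83e-05) and Zbtb7b (2.76e-14) higher. It called Cd79b (0.034) and Pecam1 (0.000532) lower in that fit. Cd79b, the most abundant B cell marker, stood at 15.5 ± 2.38 CPM in MIG and 11.8 ± 0.833 in BATF, and it was the 1 member lower at an unadjusted p under 0.05 in its list (median −0.09). Of the myeloid and dendritic cell markers, Xcr1 stood at 5.11 ± 1.15 and 8.51 ± 1.29 CPM and H2-Ab1 at 1.96 ± 1.68 and 8.46 ± 7.94 CPM, both higher at an unadjusted p under 0.05, with a list median of 0.55. EdgeR called Xcr1 without MIG replicate 2 (adjusted p = 0.0389) and H2-Ab1 without BATF replicate 2 (0.00176), and in the latter fit, where 7 members were tested, camera called the myeloid list upward (adjusted p = 0.00164, or 0.820 with an estimated correlation). Zbtb7b, the most abundant of the CD4 and regulatory T cell markers, stood at 20.4 ± 3.57 and 39.6 ± 6.55 CPM (edgeR adjusted p = 0.0658), was called by DESeq2 and by edgeR without MIG replicate 1 (0.0188), MIG replicate 2 (0.00635), BATF replicate 1 (0.0487) or BATF replicate 2 (0.00862), and was the 1 member that rose adjusted over the list alone, while Cd4 itself stood at 0.512 ± 0.0309 and 0.694 ± 0.137 CPM and the list's median was 0.12. For NK and gamma-delta T cells the most abundant marker was Zbtb16, at 1.54 ± 0.534 and 1.10 ± 0.454 CPM (list median −0.47). For erythroid, platelet and stromal cells it was Pecam1, which T cells also express, at 74.0 ± 20.2 and 57.5 ± 4.37 CPM. Without MIG replicate 2 the log2 fold change of Pecam1 was −0.62. The list's median was −0.89 over 3 tested members and −0.12 in DESeq2. With more members tested, it was −0.05 without MIG replicate 1 and −1.32 without BATF replicate 1. With all libraries 0 members of the NK and the erythroid lists passed in edgeR at an unadjusted p under 0.05, and DESeq2 called 0 members of the lists other than that of CD4 and regulatory T cells.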

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

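The list tests under upper-quartile factors and under TMM without the 50 most abundant genes and Batf were chosen after the data had been seen; each gave 3 lists, as did DESeq2 size factors. Batf kept its direction and its call in each of the 14 alternatives, from 4.90 to 5.43 on the log2 scale. The 142 calls had the same sign in every alternative that tested them. Their groups did not overlap and the alternatives reuse the same libraries, so a sign could hardly turn and this adds no support. The 3 other scalings of edgeR gave 144 to 154 calls and limma-voom 123. DESeq2 gave 345 calls (253 higher, 92 lower, 160 at least 2-fold), and no filter on low counts gave 349 (266, 83 and 184). Fewer genes were called at a mean of at least 5 CPM, 92 (76 higher, 16 lower, 53 at least 2-fold), on log2(FPKM + 1), 36 (32, 4 and 30), and on log2(FPKM + 0.1), 49 (39, 10 and 39). Of the 47 named genes besides Batf, log2(FPKM + 1) ended 20 calls and log2(FPKM + 0.1) ended 16, always in the same direction, and the cause was not tested. Leaving out 1 library gave 248 to 589 calls, 192 to 320 higher, 55 to 269 lower and 132 to 205 at least 2-fold, with 2 to 4 lists called. In these fits the lone library of a group is assumed to vary like the other group. The rise in calls was not traced to a cause. Signs turned for Jun without BATF replicate 1 (0.13, range with 1 library left out −0.67 to 0.13), Junb without BATF replicate 2 (−0.022, range to 0.31), Il7r without MIG replicate 2 (−0.22) and BATF replicate 1 (−0.16, range to 0.48), and Tox without MIG replicate 2 (0.21, range from −1.00), none of them called. Camera called 7 lists at a mean of at least 5 CPM (naive and memory T cell genes, glycolysis, interferon-stimulated genes, costimulatory molecules, fatty acid oxidation and NAD metabolism, T cell receptor signalling, and Th2, Th17 and Tfh genes), 0 with an estimated correlation (1 at an unadjusted p under 0.05), and fry called 0 (3 at an unadjusted p under 0.05).

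With the table's replicate number as a block, edgeR called 1504 genes, 916 higher, 588 lower and 298 at least 2-fold, among them all 142, with 3 lists and a Batf log2 fold change of 5.18. Differences between replicates 1 and 2 in MIG and in BATF correlated across 9361 genes (r = 0.43, genes not being independent). With 2 pairs and no label on what a number marks, the numbers are not shown to pair the libraries, and the block leaves 1 residual degree of freedom. Depth limits the test of genes under about 1 CPM, and 2 libraries per group limit the spread that can be estimated.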

Other observations

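The gene families and single genes in the next 2 paragraphs were chosen after their values were seen, and so were all tests of technical explanations below except that of little room to fall. Interferon-inducible GTPases of the IRG family, which act on pathogen vacuoles, stood outside the lists. Of 7 tested, 5 fell in BATF (Iigp1, Gm12250, Irgm1, Ifi47 and Igtp) and 0 rose, with a median log2 fold change of −0.59. Igtp went from 294 ± 11.4 to 199 ± 2.04 CPM and Ifi47 from 234 ± 9.27 to 156 ± 5.59 CPM (SD, n = 2 per group). Without BATF replicate 2 the edgeR adjusted p was 0.0620 for Gm12250, 0.132 for Ifi47, 0.115 for Igtp and 0.138 for Irgm1. Without BATF replicate 1 it was 0.101 for Igtp, while the other 3 stayed called. The interferon-responsive gene Ifi27l2a fell from 77.8 ± 5.66 to 45.3 ± 3.88 CPM (0.0504 without BATF replicate 2).

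Of 7 inhibitors of cyclin-dependent kinases tested, Cdkn1a (p21), Cdkn2a and Cdkn2b rose and 0 fell, with a median log2 fold change of 1.05. Cdkn1a went from 58.3 ± 3.94 to 120 ± 3.51 CPM and Cdkn2a from 11.2 ± 2.34 to 27.9 ± 0.383 CPM, while Cdkn1b (p27) stood at 114 CPM in both groups. Of 8 S100 calcium-binding genes of the S100a group, S100a4, S100a6 and S100a11 rose and 0 fell, with a median of 0.88. S100a4 went from 231 ± 23.1 to 487 ± 20.9 CPM, and S100a6 was not called without BATF replicate 2 (edgeR adjusted p = 0.0826). The intermediate filament gene Vim rose from 2373 ± 136 to 4300 ± 230 CPM, the most abundant transcript among the 142. Msc, a basic helix-loop-helix repressor, rose from 0.447 ± 0.0543 to 9.43 ± 5.15 CPM, Zbtb32, a repressor of lymphocyte proliferation, from 21.3 ± 1.24 to 78.1 ± 2.56 CPM, and Dusp4, a phosphatase of MAP kinases, from 4.85 ± 0.966 to 16.7 ± 1.44 CPM.

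Interferon-stimulated genes were lower in BATF, with a list median of −0.43, although camera's call (adjusted p = 2.08e-12) was lost with an estimated correlation (adjusted p = 0.301) and fry did not call the list (0.112). The list's median difference within a group was at most 0.0669 in size, against −0.34 to −0.56 across groups. This does not decide on scatter between cultures of one group. The list was chosen for its difference in these same libraries, and each group had 2 of them. Library scaling, which moves all genes alike, is argued against, since the list was shifted by −0.455 against 12466 other genes in its range of mean CPM (Hodges-Lehmann 95% interval −0.546 to −0.366, genes taken as independent), and a trend on GC content and transcript length likewise, since the median of the 25 members with enough fragments was −0.46 after removing such trends and −0.43 before. A hypothesis found and tested on the same data is that BATF may lower interferon-responsive transcription. Whether the cultures differed in interferon, and whether the retroviral preparations did, was not tested.

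More genes rose than fell, 115 of 142. Library scaling stays open, since all genes would have to be shifted by 0.17 on the log2 scale for the lower calls to reach the number of higher ones, while the 3 other scalings moved the median of all genes by at most 0.013 and so did not test it. Genes with few fragments have little room to fall. Among the 47 called genes with a mean of at least 50 CPM 74.5% were higher (exact binomial 95% interval 59.7% to 86.1%, genes taken as independent). Of the 95 below that level 84.2% were higher. Rises thus outnumbered falls at the higher level too. The interval is wide, and its lower limit just missed the share set beforehand for setting this explanation aside. How much of the excess it accounts for cannot be told. The share also rests on the threshold and the libraries, at 62.1% of the 1402 genes with an unadjusted p under 0.05 and 54.3% of the 589 called without MIG replicate 2.

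Tnfrsf8, Icos, Maf, Zbtb32 and Pparg, each also known from helper or regulatory CD4 T cells, rose together in BATF. They were grouped after their values were seen. Camera did not call the fixed list of Th2, Th17 and Tfh genes (adjusted p = 0.171). At a mean of at least 5 CPM it did (0.000236, or 0.555 with an estimated correlation). EdgeR called 0 of 4 CD4 and regulatory T cell markers with all libraries and no block. Carry-over of CD4 T cells through the CD8 sort is argued against, since the upper 95% limit of the gain of Cd4 was 4.61% of the smallest gain among the 5 genes, that of Pparg (19.3 CPM). An earlier criterion, an upper limit of the Cd4 fold change below 2, was not met (2.74), and it decides little at the 11 to 15 fragments that Cd4 had per library. Zbtb7b, another CD4 T cell marker, gained about as much as Pparg (20.4 to 39.6 CPM), and its gain taken alone goes with carry-over. It missed the threshold with all libraries (edgeR adjusted p = 0.0658). It passed in DESeq2 (0.000148), with no filter on low counts (0.00411) and with the block (2.76e-14). With 1 library left out its log2 fold change was 0.77 to 1.15. CD4 T cells would bring Cd4 as well, and MIG cells already held 20.4 CPM of Zbtb7b beside so few fragments of Cd4. An effect of BATF within CD8 T cells stays open, as does a difference between cultures, which was not tested apart from the edgeR test by which the 5 genes were chosen.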
